A study of Mus musculus with 9 samples.

How the data were processed

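RNA from brain tissue around the injection sites of 9 mice, 3 per group, was labelled and hybridized to 1 array per mouse. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column, and 5 µg was used to prepare biotin-labelled cRNA. The deposited table holds 1 intensity value per probe set and array on a linear scale, made by the authors with GCOS 1.4.0.036 per the submitters' processing notes. How the signals were summarised and scaled is not given in the sources used here. No detection calls were used here, so a gene dim on the mock arrays was not set at a bound, and its fold depends on the pseudocount.

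Signals were turned into log2(signal + 16), so that fold changes are on that scale and understate the change of dim genes. Array medians differed by more than 0.1, and each array's median was moved to the median of the 9 medians. The shift was largest for HS replicate 3, by 0.66. The 64 control probe sets were left out, as were probe sets that were not above the 40th percentile of their own array on at least 3 arrays, which left 28257 of 45101. Platform annotation gave 1 gene symbol to 34945 probe sets, several to 932 and none to 9160, and 34754 single symbols were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, with 0 symbols changed. No coordinates are given, because the array's genome build was not stated. Probe sets with several symbols name no gene. For a gene with several probe sets, the one with the highest mean over the 9 arrays stood for it, which gave 13331 genes. Probe sets of multigene families, such as the H2, Oas, Gbp, Ifi200 and Irgm families and Gm9706, can bind transcripts of near-identical relatives, and their values are uncertain in that respect.

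Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with lmFit and eBayes with an intensity trend, on all 9 arrays in 1 fit with the group as the only term. The 3 contrasts were HS against mock, MC+HS against mock and MC+HS against HS. P values were adjusted by Benjamini-Hochberg over the probe sets of each contrast, two-sided, and called under 0.05. Errors printed as ± are standard errors of the log2 difference from this fit unless named otherwise. The mice of a group are separate animals per the labels.

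Before the data were examined, 33 gene lists were fixed, with 643 entries, 584 of them named on the array. They cover interferon and antigen presentation genes, chemokines and cytokines, immune cell, glial, neuronal and vascular markers, cell death and cell cycle, stress, metabolism and repair. Some lists share genes, so their counts are not separate evidence. Ccl5 is in chemokines and NK and cytotoxic cells, and Hspb1 in reactive astrocytes and heat shock. The dendritic cell list shares Bst2 with interferon-stimulated genes and Siglech with homeostatic microglia. Lists with at least 5 measured genes were tested with camera, with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 31 lists tested. B cells, with 4 measured genes, and red blood cells, with 0, were not tested. The test was repeated with a correlation estimated per list and with fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. Since this is bulk tissue, a shift of cell type markers is given as a shift of those genes.

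The rule for named genes was also fixed beforehand. In each comparison it took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, and, where fewer than 4 genes passed in a direction, the 4 with the smallest p. A gene named in 1 comparison could be given in the others. From the list members the rule allowed, a smaller number is given in the text.

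The overlap of the responses was set beside that of independent lists and beside 100 simulations of unchanged groups against the same mock arrays. The scripts were tested on simulated data drawn from the real arrays' means and spread, with 100 probe sets changed 2-fold and 100 changed 4-fold. For HS against mock 12% and 62% were recovered, for MC+HS against mock 6% and 53%, and for MC+HS against HS 18% and 72%, with at most 1 false call per comparison. Each comparison was simulated once, so differences between their shares can come from the draw. With HS replicate 1 left out the shares were 72% and 95%, 75% and 97%, and 70% and 95%, with 9 to 11 false calls. A list raised in the simulation was called in each comparison, and 0 of 20 unchanged lists were. Simulated genes varied independently, while the correlation estimated for the real lists reached 0.872. The simulation therefore does not show how often unchanged real lists would be called.

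Alternatives fixed beforehand were pseudocounts of 1 and 64, no filter or one at the 60th percentile, quantile normalization, no intensity trend, a robust prior, array quality weights, only the 6 arrays compared, the replicate number as a block, leaving out each array in turn, leaving out probe sets that can match several transcripts, a 2-fold minimum, an estimated correlation, fry, and the mean of a gene's probe sets. Chosen after seeing the data were scaling to a trimmed mean before the log, and settings that leave out HS replicate 1 together with quantile normalization, trimmed-mean scaling, mock replicate 2, array quality weights or a replicate block. No slide, scan date or other batch was given in the sources used here.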

Results

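Gene expression was measured in the brains of adult male BALB/c mice injected into the striatum with BV-HSVtk, a vector made from a baculovirus, an insect virus. The series set out to compare the expression changes that followed vector purified in different ways. In the HS group the vector had been purified by high-speed centrifugation alone, and in the MC+HS group by membrane chromatography and high-speed centrifugation. The mock group received medium of Sf9 insect cells, free of baculovirus, that had been taken through the MC+HS purification. Vector-injected mice received 100000000 viral particles in 10 µL on each side, and tissue around the injection sites was collected after 2 days. Each group held 3 mice and 3 arrays, labelled as biological replicates, so n = 3 per group throughout unless an array is said to be left out. The arrays carried 45101 probe sets, of which 28257 passed the filter on dim probe sets, and the median signal per array ranged from 147 to 263 intensity units. With 3 arrays per group, the median 95% confidence interval of a log2 difference reached 0.603 to either side. Without HS replicate 1, described below, it reached 0.325 in the comparisons with HS and 0.290 for MC+HS against mock.

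HS replicate 1 stood apart from the other 8 arrays. Its median correlation with the others was 0.805, against 0.972 to 0.982 for the rest, and the standard deviation of its log2 signals was 1.54, against 2.17 to 2.39. Bacterial transcripts spiked into every hybridization were out of order on this array: bioD gave 0.677 times the signal of bioC (3' probe sets), against 3.35 to 3.67 times on the other arrays. Its Gapdh 3'/5' ratio was 2.00, against 0.865 to 0.932. The array stayed in the analysis fixed before the data were examined, and results with each array left out had been foreseen, and the main counts are given with and without it.

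**Figure D1:**
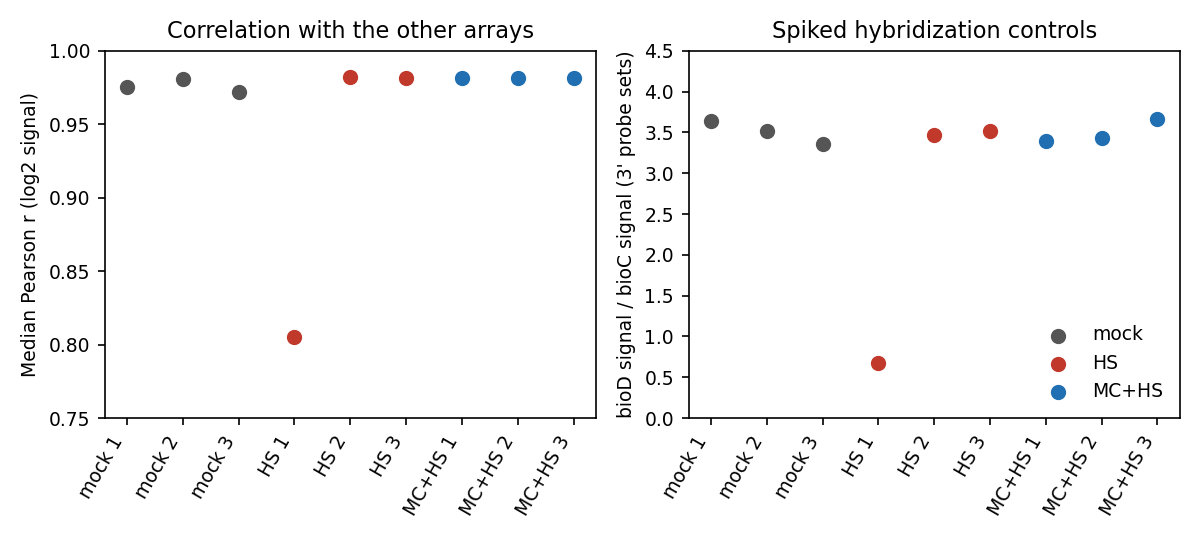
Median Pearson correlation of each array's log2 signals with the other arrays (left) and ratio of the spiked bacterial controls bioD and bioC (right, 3' probe sets), 1 point per array, coloured by group. HS replicate 1 lies at 0.805 and 0.677, below every other array in both panels.

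HS against mock asked which genes responded to the vector purified by centrifugation alone. The mock medium had been taken through the MC+HS purification, so vector and purification differed together in this comparison and cannot be told apart. The largest rises were in immune genes. Ccl5, a chemokine that draws T cells and monocytes, was 44.2-fold higher (log2 change 5.47 ± 0.72, SE; limma, Benjamini-Hochberg adjusted p = 0.0114), and Gzmb, the cytotoxic protease granzyme B, was 28.1-fold higher (4.81 ± 0.55, adjusted p = 0.00603). The chemokine Ccl7 rose 17.3-fold with the smallest adjusted p of the comparison (4.11 ± 0.19, adjusted p = 0.000135). Cxcl11, Acod1, Ifi204, Ccl2 and the predicted gene Gm9706 completed the 8 largest rises, with log2 changes of 4.16, 4.08, 4.02, 3.99 and 3.83. The 5 genes that fell were Serpinb1a (log2 change -1.51 ± 0.23), Arap2 (-1.50 ± 0.24), the microglial receptor gene Gpr34 (-1.26 ± 0.17), Fmod (-1.18 ± 0.20) and AW047730 (-1.01 ± 0.18), with limma adjusted p of 0.0203, 0.0303, 0.0125, 0.0356 and 0.0429.

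Among interferon-stimulated genes, 14 of 37 measured members rose and none fell, or 34 adjusted over the list alone, and the median member was 5.01-fold above mock. The list moved as a group (camera adjusted p = 8.77e-65), also with an estimated correlation (adjusted p = 0.0415). Ifih1, a sensor of double-stranded RNA, rose by 3.02 ± 0.31 on the log2 scale (limma adjusted p = 0.00409), Oasl1 by 2.32 ± 0.23 and Oas3, a double-stranded RNA sensor upstream of RNase L, by 2.29 ± 0.25. Of the interferon-gamma-inducible GTPases and regulators, 7 of 15 rose, or 13 adjusted over the list alone (camera adjusted p = 5.12e-34, and adjusted p = 0.0377 with an estimated correlation). Iigp1 rose by 3.42 ± 0.33, Gbp7 by 2.74 ± 0.29, Irgm1 by 2.54 ± 0.30 and Cd274, which encodes the immune checkpoint ligand PD-L1, by 2.22 ± 0.27. For MHC class I presentation 5 of 13 members rose, or 9 adjusted over the list alone. They included the peptide transporter genes Tap2 (2.88 ± 0.31) and Tap1 (2.55 ± 0.35) and the class I heavy chain gene H2-D1 (2.38 ± 0.35), whose near-identical relatives can share probes. This list passed with the preset correlation (camera adjusted p = 1.81e-20) and missed the threshold with an estimated one (adjusted p = 0.0578). None of the 8 measured MHC class II genes passed (camera adjusted p = 0.449), and Cd74, the class II invariant chain, differed by 0.13 ± 0.18 (limma adjusted p = 0.737). With HS replicate 1 left out, 36 of 37 interferon-stimulated genes, 12 of 15 GTPases and regulators and 13 of 13 MHC class I genes rose over all genes. With an estimated correlation none of these lists then passed (camera adjusted p = 0.084, 0.084 and 0.0926), while with fry all of them did (adjusted p = 0.00266, 0.00156 and 0.00328).

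Chemokines had 9 of 20 members higher, or 14 adjusted over the list alone, with a median log2 change of 1.79 (camera adjusted p = 3.00e-28, and adjusted p = 0.0377 with an estimated correlation). Cxcl9 rose by 3.78 ± 0.32. Of the inflammatory cytokines and NF-kB targets, 5 of 23 rose, or 11 adjusted over the list alone (camera adjusted p = 7.49e-25, and 0.0377 as an adjusted p with an estimated correlation). They included the endothelial adhesion gene Selp (2.52 ± 0.21), the cytokine Il6 (2.79 ± 0.29), Icam1 (2.00 ± 0.27) and Bcl3 (1.44 ± 0.21). Markers of NK and cytotoxic cells rose in 3 of 10 cases, or 7 adjusted over the list alone (camera adjusted p = 6.22e-14, and adjusted p = 0.0377 with an estimated correlation), with Gzma at 3.49 ± 0.31. For infiltrating monocytes the count was 2 of 14, or 8 adjusted over the list alone, namely Chil3 (3.14 ± 0.31) and Ccr1 (1.63 ± 0.17). For neutrophils it was 2 of 10, or 2 adjusted over the list alone, namely the calprotectin genes S100a8 (2.19 ± 0.25) and S100a9 (2.18 ± 0.25). Both lists passed (camera adjusted p = 9.62e-14 and 8.87e-07), also with an estimated correlation (adjusted p = 0.0415 and 0.0377). Of the cell death list, 3 of 16 members rose, or 7 adjusted over the list alone. They were Casp4 (3.80 ± 0.27), which senses cytosolic lipopolysaccharide, the necroptosis effector gene Mlkl (3.21 ± 0.25) and the pyroptosis pore gene Gsdmd (1.65 ± 0.27). That list passed with the preset (camera adjusted p = 3.50e-15) and with an estimated correlation (adjusted p = 0.045). T cell markers had no member past the threshold in 9 measured (camera adjusted p = 0.996), nor did dendritic cell markers in 8 (camera adjusted p = 0.505). With HS replicate 1 left out, the numbers that rose were 15 of 20 chemokines, with 1 lower, 14 of 22 cytokines and NF-kB targets, 4 of 10 NK and cytotoxic, 7 of 13 monocyte, 3 of 10 neutrophil and 9 of 16 cell death genes. With an estimated correlation the adjusted p of these lists were then 0.084, and 0.214 for neutrophils, and with fry they lay between 0.00156 and 0.0035.

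Reactive astrocyte, complement, microglial, pattern recognition and matrix lists passed with the preset correlation and not with an estimated one. Reactive astrocyte genes had 2 of 20 members higher, or 12 adjusted over the list alone (camera adjusted p = 6.67e-20, adjusted p = 0.102 with an estimated correlation), namely the oncostatin M receptor gene Osmr (1.42 ± 0.25) and Steap4 (2.88 ± 0.53). Complement had 2 of 12, or 3 adjusted over the list alone, namely Cfb (2.53 ± 0.30) and C1ra (2.59 ± 0.35), with camera adjusted p = 5.73e-07 and adjusted p = 0.313 with an estimated correlation. Of activated macrophage or microglia genes 1 of 23 rose, Ncf4, an NADPH oxidase subunit (1.56 ± 0.16), or 3 adjusted over the list alone. Of homeostatic microglia genes 1 of 13 fell, Gpr34, or 4 adjusted over the list alone, and P2ry12, the microglial ADP receptor gene, differed by -0.74 ± 0.16 (limma adjusted p = 0.107). These lists gave camera adjusted p = 1.41e-09 and 0.00356, and adjusted p = 0.313 and 0.414 with an estimated correlation. Pattern recognition genes had 0 of 22 past the threshold, or 6 adjusted over the list alone (camera adjusted p = 1.91e-14, adjusted p = 0.0515 with an estimated correlation). In matrix and wound repair 2 of 23 rose, or 5 adjusted over the list alone, with 1 lower, namely Mmp3 (1.39 ± 0.23) and Tgfbi (1.79 ± 0.31), with camera adjusted p = 1.95e-06 and adjusted p = 0.209 with an estimated correlation. Most of these counts depended on HS replicate 1, where reactive astrocyte genes averaged 0.15 over mock, against 1.61 and 1.75 on the other HS arrays. Leaving it out, 16 of 20 reactive astrocyte, 7 of 12 complement, 8 of 23 activated macrophage or microglia, 10 of 21 pattern recognition and 6 of 22 matrix and wound repair genes rose and 4 of 13 homeostatic microglia genes fell, with estimated-correlation adjusted p between 0.084 and 0.326.

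With all 9 arrays no member passed in the other lists, over all genes or within the list, except for 1 choroid plexus and ependyma gene and 1 dendritic cell gene that were lower when adjusted over the list alone. Endothelium and pericytes and cell cycle shifted upward (camera adjusted p = 0.000158 and 0.000539) and striatal medium spiny neurons, mitochondrial respiratory chain and cholesterol synthesis downward (camera adjusted p = 0.0483, 0.0264 and 0.0129). With an estimated correlation their adjusted p were 0.446, 0.389, 0.775, 0.775 and 0.647. Several of the downward shifts moved with HS replicate 1: its medium spiny neuron genes averaged -1.92 against mock, HS replicates 2 and 3 -0.16 and 0.11, and its respiratory chain genes -2.04, against -0.09 and -0.02. Without that array the respiratory chain and cholesterol synthesis were still called lower (camera adjusted p = 0.0161 and 0.000656). With an estimated correlation their adjusted p were then 0.643 and 0.264. Camera gave adjusted p between 0.0581 and 0.987 for choroid plexus and ependyma, cortical excitatory neurons, pan-neuronal genes, astrocyte identity, oligodendrocytes and myelin, oligodendrocyte precursors, immediate early genes and the heat shock and unfolded protein response. With HS replicate 1 left out, cell cycle and medium spiny neurons were not called (camera adjusted p = 0.0784 and 0.11), and T cells, cortical excitatory neurons, choroid plexus and ependyma and immediate early genes were called lower and heat shock higher (camera adjusted p = 0.0179, 0.0261, 0.00122, 0.0111 and 5.36e-05, and 0.12, 0.334, 0.355, 0.501 and 0.084 as adjusted p with an estimated correlation). In that fit 3 of 18 endothelium and pericyte, 4 of 19 heat shock, 2 of 14 astrocyte identity, 1 of 14 oligodendrocyte and myelin, 1 of 17 immediate early and 1 of 8 dendritic cell genes rose over all genes, and 1 of 10 choroid plexus and ependyma and 1 of 8 dendritic cell genes fell.

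In all, 211 probe sets were higher and 8 lower at a limma adjusted p under 0.05, and 1886 passed an unadjusted 0.05. They covered 119 genes higher and 5 lower. Camera called 20 of 31 lists, 16 upward and 4 downward, 8 of them also with an estimated correlation. The counts were 830 higher and 100 lower without HS replicate 1. There 23 lists were called, none with an estimated correlation (smallest adjusted p = 0.084). Fry called 9 lists with all 9 arrays and 16 without HS replicate 1 (smallest adjusted p = 0.00561 and 0.00156). Leaving out any other array but mock replicate 2 gave between 67 and 133 probe sets. A fit of the 6 compared arrays alone gave 15. Ccl7, Gzmb, Acod1, Ifi204, Oas3, Cxcl9, Selp, Il6, Gzma, Chil3, Ccr1, S100a8, S100a9, Casp4, Mlkl, Steap4, Mmp3 and Bcl3 lay among the dimmest 40% of probe sets on all 3 mock arrays, so the size of their folds depends on the pseudocount of 16.

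MC+HS against mock asked the same of the vector that had also passed through membrane chromatography. Ccl5 was 33.9-fold higher (log2 change 5.08 ± 0.72; limma adjusted p = 0.0207) and Gzmb 21.7-fold higher (4.44 ± 0.55, adjusted p = 0.0118). Ifi47, an interferon-inducible GTPase gene, rose 18.3-fold (4.20 ± 0.72, adjusted p = 0.0453). Cxcl11 (4.11 ± 0.49), Gm9706 (3.81 ± 0.58), Ifi204 (3.78 ± 0.49), Casp4 (3.49 ± 0.27) and the guanylate-binding protein gene Gbp6 (3.47 ± 0.58) came next among the genes that passed, and Ccl7 again had the smallest adjusted p (3.35 ± 0.19, adjusted p = 0.000824). The 3 genes that fell were AW047730 (-1.05 ± 0.18), Gpr34 (-1.03 ± 0.17) and P2ry12 (0.501 times the mock level, SE 0.16 on the log2 scale), with limma adjusted p of 0.0448, 0.0425 and 0.0351. Siglech, another microglial gene, differed by -1.09 ± 0.20 and did not pass (limma adjusted p = 0.0606).

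Interferon-stimulated genes rose in 13 of 37 cases, or 35 adjusted over the list alone, with a median log2 change of 2.33 (camera adjusted p = 8.72e-81, and adjusted p = 0.0301 with an estimated correlation). Oasl1 rose by 2.09 ± 0.23, Oas3 by 2.19 ± 0.25 and Ifih1 by 2.63 ± 0.31. Of the interferon-gamma-inducible GTPases and regulators 8 of 15 rose, or 13 adjusted over the list alone (camera adjusted p = 3.81e-37, adjusted p = 0.0301 with an estimated correlation), among them Iigp1 (2.95 ± 0.33), Cd274 (2.23 ± 0.27) and Irgm2 (2.19 ± 0.29). MHC class I presentation had 3 of 13 higher, or 10 adjusted over the list alone, namely Tap1 (2.99 ± 0.35), Tap2 (2.70 ± 0.31) and H2-D1 (2.43 ± 0.35), and passed with both the preset (camera adjusted p = 2.68e-26) and an estimated correlation (adjusted p = 0.0418). MHC class II genes had none of 8 past the threshold (camera adjusted p = 0.515). In the fit without HS replicate 1, 37 of 37 interferon-stimulated genes, 11 of 15 GTPases and regulators and 13 of 13 MHC class I genes rose over all genes. Each list then had a camera adjusted p of 0.0784 with an estimated correlation, while all of them passed with fry (adjusted p = 0.00337, 0.00261 and 0.00391).

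Chemokines had 8 of 20 members higher, or 15 higher and 1 lower adjusted over the list alone. The inflammatory cytokines and NF-kB targets had 5 of 23 higher, or 12 adjusted over the list alone, among them Selp (1.95 ± 0.21), Il6 (2.02 ± 0.29) and Socs3, a feedback inhibitor of cytokine signalling (2.20 ± 0.33). NK and cytotoxic cell markers had 3 of 10, or 4 adjusted over the list alone, with Gzma at 2.77 ± 0.31. Infiltrating monocyte markers had 2 of 14, or 5 adjusted over the list alone, namely Chil3 (2.97 ± 0.31) and Ccr1 (1.41 ± 0.17), and the cell death list 2 of 16, or 7 adjusted over the list alone, namely Casp4 and Mlkl (2.53 ± 0.25). These 5 lists gave camera adjusted p = 6.15e-29, 3.12e-24, 6.72e-12, 8.78e-16 and 1.97e-17, and adjusted p = 0.0301, 0.0301, 0.0301, 0.0301 and 0.0373 with an estimated correlation. Neutrophil markers had 1 of 10 higher, S100a9 (1.47 ± 0.25, limma adjusted p = 0.0454), or 2 adjusted over the list alone, while S100a8 was at 1.27 ± 0.25 and did not pass (limma adjusted p = 0.085). The neutrophil list passed with the preset correlation (camera adjusted p = 0.000171) and not with an estimated one (adjusted p = 0.0551). In the fit without HS replicate 1, 15 of 20 chemokines rose and 1 fell, 13 of 22 cytokines and NF-kB targets rose and 1 fell, and 4 of 10 NK and cytotoxic, 6 of 13 monocyte, 8 of 16 cell death and 3 of 10 neutrophil genes rose. With an estimated correlation the adjusted p of these lists were then 0.0784, and 0.188 for neutrophils, and with fry they lay between 0.00261 and 0.00917.

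Reactive astrocyte genes had 0 of 20 past the threshold over all genes and 14 adjusted over the list alone, with Osmr at 1.38 ± 0.25 and Steap4 at 2.88 ± 0.53 (limma adjusted p = 0.0597 and 0.0578). Complement had 2 of 12 higher, Cfb (2.89 ± 0.30) and C1ra (2.64 ± 0.35), or 5 adjusted over the list alone. Activated macrophage or microglia genes had 1 of 23 higher, Ncf4 (1.58 ± 0.16), or 7 adjusted over the list alone, and homeostatic microglia genes 2 of 13 lower, Gpr34 and P2ry12, or 4 adjusted over the list alone. Pattern recognition had 0 of 22 over all genes and 8 adjusted over the list alone, and matrix and wound repair 0 of 23 over all genes, with 5 higher and 1 lower adjusted over the list alone. Camera adjusted p for these 6 lists were 3.24e-28, 3.16e-12, 7.36e-13, 2.78e-06, 7.36e-13 and 1.52e-06. With an estimated correlation the adjusted p were 0.0551, 0.15, 0.18, 0.174, 0.0553 and 0.174. In the fit without HS replicate 1, 16 of 20 reactive astrocyte, 7 of 12 complement, 8 of 23 activated macrophage or microglia, 7 of 21 pattern recognition and 6 of 22 matrix and wound repair genes rose over all genes and 4 of 13 homeostatic microglia genes fell, with estimated-correlation adjusted p between 0.0784 and 0.298.

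With all 9 arrays the remaining lists had no member past the threshold over all genes. Endothelium and pericytes, immediate early genes and the heat shock and unfolded protein response moved upward (camera adjusted p = 1.12e-05, 0.0234 and 0.025), and choroid plexus and ependyma and cholesterol synthesis downward (camera adjusted p = 1.52e-06 and 0.000416). With an estimated correlation none of the 5 passed (adjusted p = 0.346, 0.59, 0.673, 0.18 and 0.387). The choroid plexus and ependyma genes also varied within the mock group, where they averaged 0.44, 0.49 and -0.93 on the log2 scale around the group mean. Camera gave adjusted p of 0.103 or more for T cells, dendritic cells, cell cycle, the respiratory chain, astrocyte identity, oligodendrocytes and myelin, oligodendrocyte precursors and the pan-neuronal, medium spiny neuron and cortical excitatory neuron lists. Medium spiny neurons, cortical excitatory neurons and the respiratory chain were called lower in the fit without HS replicate 1 (camera adjusted p = 0.0113, 0.0351 and 0.0007, and 0.525, 0.349 and 0.497 as adjusted p with an estimated correlation). There 3 of 18 endothelium and pericyte, 1 of 19 heat shock, 1 of 17 immediate early, 1 of 14 astrocyte identity and 1 of 8 dendritic cell genes rose over all genes, and 2 of 14 astrocyte identity, 1 of 10 choroid plexus and ependyma, 1 of 18 medium spiny neuron and 1 of 8 dendritic cell genes fell.

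In all, 157 probe sets were higher and 7 lower at a limma adjusted p under 0.05, and 1383 passed an unadjusted 0.05. They covered 92 genes higher and 3 lower. Camera called 20 of 31 lists, 17 upward and 3 downward, 8 of them also with an estimated correlation. Without HS replicate 1, which enters through the shared estimate of the spread, 701 probe sets were higher and 233 lower, and 23 lists were called, none with an estimated correlation (smallest adjusted p = 0.0784). A fit of the 6 compared arrays alone gave 727, while leaving out 1 of the MC+HS arrays, mock replicate 1, mock replicate 3 or HS replicate 2 gave between 10 and 87.

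**Figure D2:**
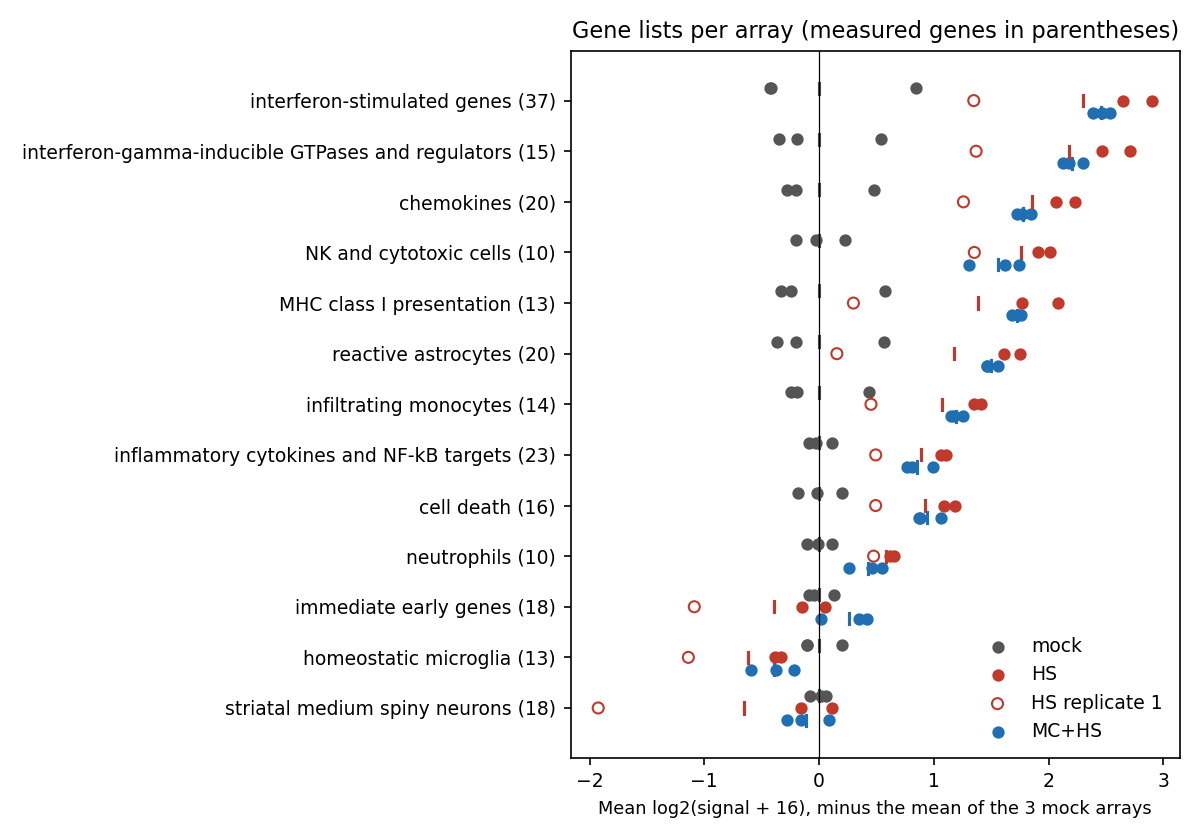
Mean log2(signal + 16) of the measured genes of 13 fixed lists on each array, minus the mean of the 3 mock arrays, with 1 point per array, an open circle for HS replicate 1 and a vertical tick at each group's mean. For interferon-stimulated genes the MC+HS arrays lie at 2.39 to 2.53, HS replicates 2 and 3 at 2.65 and 2.90, HS replicate 1 at 1.35, and the mock arrays at -0.43, 0.85 and -0.42.

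The responses to both preparations overlapped. Of the probe sets higher after MC+HS, 148 of 157 were also higher after HS, among them those of Ccl5, Gzmb, Cxcl11, Ccl7, Casp4 and Iigp1, and 3 were lower in both, so that 151 were shared and 0 moved in opposite directions. Independent lists of these sizes would share 1.17 probe sets, and 100 simulations of unchanged groups against the same mock arrays shared 0. Unchanged groups give few calls, so that 0 tells little of what the shared mock arrays add. Log2 changes of the comparisons correlated across probe sets, which are not independent replicates, at r = 0.635, against a median of 0.223 in the simulations, and their covariance was 0.108, against 0.0163. The shared count was 669 without HS replicate 1, against 21.6 for independent lists, and r was 0.846, against 0.447 in simulations. Leaving out any other array but mock replicate 2 lowered the shared count to between 10 and 61, and fits of only the 6 arrays compared gave 15. The 3 mock arrays could not be split into parts of at least 2, so part of the excess may come from the shared controls.

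MC+HS against HS was the comparison that the series named as its aim. No gene passed the test. Among genes lower after MC+HS, the smallest unadjusted p was that of Ccl7, which was 0.59 times as high after MC+HS as after HS (log2 difference -0.76 ± 0.19; limma adjusted p = 0.728), and S100a8 (-0.92 ± 0.25), Acod1, which makes the metabolite itaconate in activated macrophages (-0.87 ± 0.25), and Itih2 (-0.63 ± 0.18) had the next smallest p and the same adjusted p. Among genes higher after MC+HS, the smallest unadjusted p was that of Arap2, a GTPase-activating protein gene, at 2.99-fold (1.58 ± 0.24, limma adjusted p = 0.728). It was at 10.13, 9.48 and 9.69 on the log2 scale on the HS arrays, at 11.21 to 11.48 on the MC+HS arrays and at 11.13 to 11.34 on the mock arrays. Zfp90 (0.60 ± 0.14), Nppc, which encodes C-type natriuretic peptide (0.68 ± 0.17), and Zdhhc1 (0.58 ± 0.15) had the next smallest p and did not pass. Genes with larger differences and larger p included Psmb10, a subunit of the immunoproteasome, at 1.66 with all arrays and -0.29 without HS replicate 1. Arap2 was the 1 gene that passed without HS replicate 1, at 1.76 on the log2 scale (limma adjusted p = 0.000418).

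**Figure D3:**
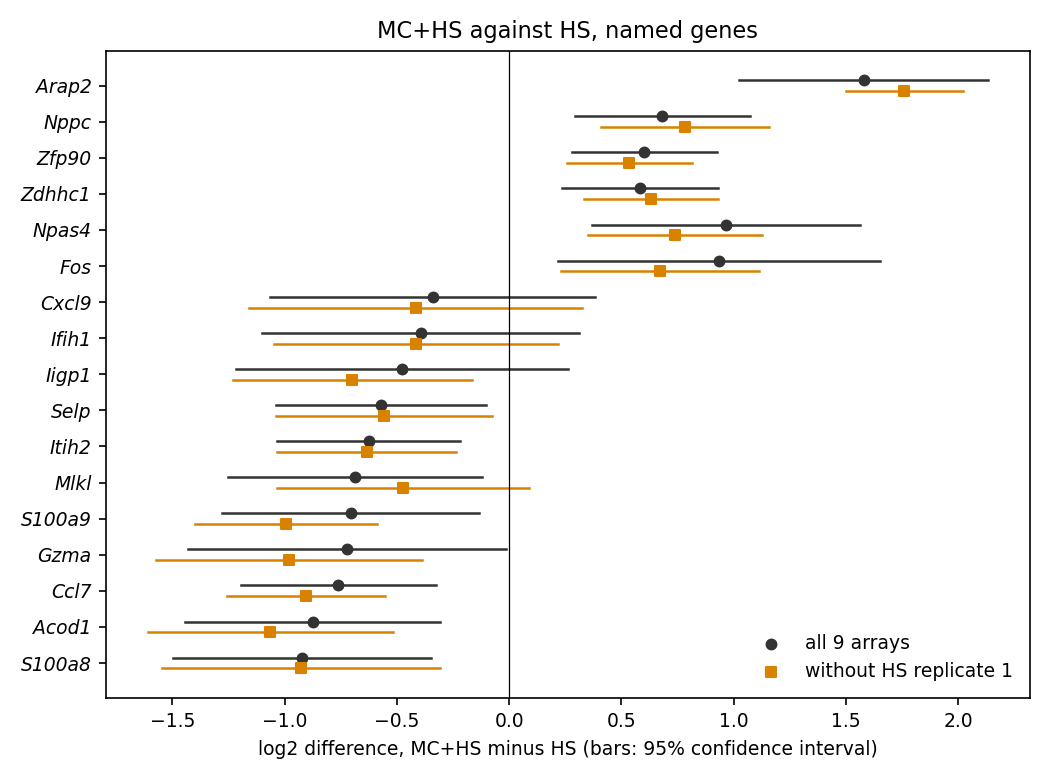
Log2 difference between MC+HS and HS for 17 named genes, with bars for the 95% confidence interval (unadjusted), with all 9 arrays (circles) and without HS replicate 1 (squares). Ccl7 lies at -0.76 and -0.91, S100a9 at -0.71 and -0.99, and Arap2 at 1.58 and 1.76.

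Camera called 10 of 31 lists between the purifications, 9 lower and 1 higher after MC+HS, and none with an estimated correlation (smallest adjusted p = 0.415) or with fry (smallest adjusted p = 0.874). The lists lower relative to other genes were interferon-stimulated genes, interferon-gamma-inducible GTPases and regulators, chemokines, inflammatory cytokines and NF-kB targets, pattern recognition, neutrophils, NK and cytotoxic cells, cell death and cell cycle. Their camera adjusted p were 0.0125, 0.00171, 4.30e-06, 5.67e-05, 0.00746, 0.00043, 0.000127, 0.00902 and 0.00133, and their adjusted p with an estimated correlation 0.999, 0.799, 0.781, 0.781, 0.793, 0.415, 0.415, 0.793 and 0.793. With all 9 arrays no member of these lists passed the limma test over all genes or adjusted over the list alone, and without HS replicate 1 none passed over all genes, while 2 chemokines, 2 neutrophil genes and 1 NK and cytotoxic gene were lower adjusted over the list alone. The median probe set lay 0.19 higher after MC+HS than after HS on the log2 scale, and -0.05 without HS replicate 1, and the test is relative to other genes. Thus 4 of the called lists had a median above 0 while the test pointed downward: interferon-stimulated genes (0.11), the GTPases (0.09), pattern recognition (0.01) and cell cycle (0.08), and the cell death list had a median of -0.01 and a mean of 0.02. Without HS replicate 1 all 9 medians were below 0, between -0.10 and -0.41, and 6 of the 9 lists were called lower, along with astrocyte identity (-0.12, camera adjusted p = 0.0359), while neutrophils, cell death and cell cycle were not. None of these 7 lists passed with an estimated correlation (adjusted p between 0.838 and 0.965).

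Immediate early genes, which neurons induce on activity, were the list that was higher after MC+HS (median log2 difference 0.63; camera adjusted p = 0.000207, adjusted p = 0.793 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. Btg2 differed by 1.30 ± 0.47, Npas4 by 0.97 ± 0.26, Fos by 0.93 ± 0.32 and Nr4a1 by 0.69 ± 0.25, each with a limma adjusted p of 0.728. The list averaged 0.42, 0.35 and 0.02 against mock on the MC+HS arrays and -1.09, -0.15 and 0.05 on the HS arrays, and without HS replicate 1 its median difference was 0.29 (camera adjusted p = 4.48e-10, adjusted p = 0.838 with an estimated correlation), with 0 of 17 members past the threshold over all genes and 7 higher and 1 lower adjusted over the list alone. For the remaining 21 lists camera gave an adjusted p of 0.0515 or more.

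In all, 0 of 28257 probe sets passed between the purifications (limma, smallest adjusted p = 0.728), and 847 passed an unadjusted 0.05. These counts were 1 and 2140 of 27973 without HS replicate 1. A missed threshold does not show that the preparations acted alike: in 1 simulated data set 2-fold differences were recovered in 18% of cases and 4-fold ones in 72%, or 70% and 95% without HS replicate 1.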

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

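The tests that weigh explanations in this part were chosen after the results were seen. The counts over other splits of the arrays were planned.

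The test of the difference between the purifications set apart 10 gene lists with the preset correlation, although no single gene passed, and none of the 10 with an estimated correlation (adjusted p between 0.415 and 0.999, and 0.793 for immediate early genes). Their median log2 differences, MC+HS minus HS, were 0.11 for interferon-stimulated genes, 0.0860 for interferon-gamma-inducible GTPases and regulators, -0.0924 for chemokines, -0.0020 for inflammatory cytokines and NF-kB targets, 0.0068 for pattern recognition and signalling, -0.0129 for neutrophils, -0.23 for NK and cytotoxic cells, -0.0063 for cell death, 0.0846 for cell cycle and 0.63 for immediate early genes. The first 9 were called lower relative to other genes and the last higher.

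For the lower immune lists, the tables argue against the deviant array HS replicate 1 as the whole cause, since 6 of the 9 lists were also called lower without it with the preset correlation, though none with an estimated one (adjusted p between 0.838 and 0.965). Array brightness or normalization stays open: with quantile normalization 4 of the 9 were called lower with all arrays and 7 without HS replicate 1, the interferon-stimulated, GTPase, chemokine and cytokine lists in both, while a first form of this test, on the interferon-stimulated list's median alone (-0.22 without HS replicate 1), had argued against it. Members of a list varying together between arrays remain a candidate explanation: with the correlation estimated per list the smallest adjusted p was 0.415. That test decides little for small differences. With all 9 arrays it passed 8 lists in each comparison with mock. Without HS replicate 1 it passed none there, although 37 of 37 interferon-stimulated genes rose after MC+HS (camera adjusted p = 0.0784 with an estimated correlation). With HS replicate 1 left out, 2 lists of any kind were called between the purifications with a replicate block and 1 with array quality weights. In each of these settings 8 of the lists called with all arrays lost their call. For neutrophils the test direction turned without a call, while the median stayed negative. With the block, 1 of the 2 called lists was newly called. So at most 1 of the 9 lower lists kept its call in either setting, and the counts do not show whether any did. The argument from the 6 lists therefore rests on fits without a block or array weights. A weaker response to the further purified vector, which the design names, stays open, with 2 intact HS arrays against 3 MC+HS arrays.

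The real split gave 10 lists between the purifications, and the highest of the other splits gave 9, so that 1 of 10 splits, the real one, gave as many. For HS against mock the real split gave 20 lists and the highest other split 20, with 3 of 10 splits as large. For MC+HS against mock these were 20 and 21, with 2 of 10. With 10 splits of 6 arrays a share under 0.05 cannot be reached.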

How the results depend on the processing

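Trimmed-mean scaling and the settings that leave out HS replicate 1 together with another choice were chosen after seeing the data. Of the genes named in the text, 47 were called for HS against mock and 39 for MC+HS against mock, and no call changed sign in any setting. Leaving out 1 array ended at most 22 and 35 of these calls (mock replicate 3 and MC+HS replicate 2), and leaving out HS replicate 1 ended 0. A fit of only the 6 arrays compared ended 41 calls for HS. Whichever array was left out, 23 and 4 kept their call, and 6 and 4 did in every setting. Of 20 called lists in each, 15 and 17 kept their call in every setting with a preset correlation. The robust prior was not run for lists, where camera has none. The number of arrays and genes dim on the mock arrays, for which no background call was used, limit the folds.

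For HS against mock (219 probe sets), MC+HS against mock (164), MC+HS against HS (0) and their overlap (151), leaving out 1 array gave 67 to 930, 10 to 934, 0 to 1 and 10 to 669. Only the 6 arrays compared gave 15 for HS, 727 for MC+HS and 15 shared, where the HS replicate 1 spread enters or leaves the fit. The 60th percentile filter gave 136 for HS. Array quality weights did not converge (weight 0.0148 for HS replicate 1, 48.7 for HS replicate 2) and gave 7776, 2146, 6536 and 1502, so that the HS mean rested on 1 array. With HS replicate 1 left out, quantile normalization gave 1026, 1232, 1 and 758, trimmed-mean scaling 859, 960, 1 and 663, leaving out mock replicate 2 as well 1065, 984, 1 and 815, array quality weights 1410, 1474, 15 and 796, and a replicate block 977, 1049, 2 and 657. The share of called probe sets that were higher went from 89.2% to 77.7% for HS with quantile normalization in place of median alignment in that setting. The cause was not tested.

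The replicate numbers did not pair the samples throughout. Correlations of deviations from the group means ran from -0.17 to 0.29 for same-numbered arrays, with 2 of 9 over 0.1. For differently numbered arrays they ran from -0.32 to 0.16, with 7 of 18 over 0.1. The highest were MC+HS 3 with mock 3 (0.29) and MC+HS 1 with mock 1 (0.26), so a pairing stays open for these. With the replicate block, 95 probe sets passed for MC+HS against mock and 93 were shared, and other counts stayed within 1.5 times.

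For lists, an estimated correlation gave 8, 8 and 0 and fry 9, 10 and 0 for HS against mock, MC+HS against mock and MC+HS against HS. Without HS replicate 1 an estimated correlation gave 0, 0 and 0 and fry 16, 16 and 0, in the same order. For MC+HS against HS, 5 were called without a filter, 5 with quantile normalization, 1 with array quality weights, 4 to 11 leaving out 1 array, and, without HS replicate 1, 1 with array quality weights and 2 with a replicate block. The direction of the list test, which for camera is relative to other genes, turned as follows, with medians. Among these lists the median itself changed sign only for astrocyte identity (0.34 with all arrays) and heat shock (0.44). T cells in HS against mock, at -0.27 and not called with all arrays, were called lower at -0.13 without HS replicate 1 (-0.42 to -0.13 leaving out 1 array). They were also called lower with trimmed-mean scaling (-0.12), mock replicate 2 left out (-0.18), array quality weights (-0.16) or the block (-0.12) besides. In MC+HS against HS, astrocyte identity was lower at -0.12 without HS replicate 1 (-0.12 to 0.65 leaving out 1 array), and at -0.12 without mock replicate 2 too, where the heat shock list was at -0.12. There fry turned interferon-stimulated genes (0.11) and pattern recognition (0.00677) upward, and neutrophils turned, at -0.0440 with array quality weights and -0.0125 with the block, both without HS replicate 1. Ccdc153 was called at -0.59 with array quality weights. The cause was not tested.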

Other observations

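The tests that weigh explanations in this part were chosen after the results were seen, as was the setting without both HS replicate 1 and mock replicate 2. The fit without HS replicate 1 and the counts over other splits of the arrays were planned.

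With HS replicate 1 left out, markers of endothelium and pericytes rose in 3 of 18 cases after HS and in 3 of 18 after MC+HS, or 10 and 9 adjusted over the list alone. The tight junction gene Cldn5 was higher by 1.13 on the log2 scale after HS (limma adjusted p = 0.000346) and by 0.96 after MC+HS (adjusted p = 0.000536), and the endothelial cadherin gene Cdh5 by 0.84 and 0.86 (adjusted p = 0.0309 and 0.0151). Camera called the list upward in both (adjusted p = 7.94e-07 and 4.74e-06), and not with an estimated correlation (adjusted p = 0.167 and 0.189). The small heat shock protein gene Hspb1 was higher by 1.32 and 1.12 (limma adjusted p = 0.000658 and 0.00104), in a heat shock and unfolded protein list with 4 of 19 members higher after HS and 1 of 19 after MC+HS. With all 9 arrays Cldn5, Cdh5 and Hspb1 did not pass in either comparison.

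In the same 8 arrays, homeostatic microglia genes fell in 4 of 13 cases in each comparison with mock, namely Gpr34, P2ry12, Siglech and Fcrls. Fcrls, a microglial Fc receptor-like gene, was at -1.87 after HS and -1.59 after MC+HS on the log2 scale (limma adjusted p = 0.002 and 0.00316). Medium spiny neuron genes had 0 of 18 past the threshold after HS and 1 lower after MC+HS, and pan-neuronal genes 0 of 19 in both.

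HS replicate 1 departed from the other 8 arrays in correlation, range and control probe sets. A different distribution of signals is argued against as the whole cause, because quantile normalization left its median correlation at 0.813, against 0.973 to 0.982 for the others. Overall brightness was not decided by this test, since a plain shift of log2 signals hardly changes a correlation. The median signal of this array, 161 units, lay within the 147 to 263 of the others, and its trimmed mean of 278 lay below their 481 to 909. Degraded mouse RNA is argued against as the whole cause, because it would leave the spiked bacterial controls in order, and bioD was 0.677 times bioC with the 3' probe sets. A fault in hybridization or reading of that array stays open. With the 5' probe sets bioD was 0.475 times bioC, against 3.40 to 4.17 on the others. These probe sets measure the same spiked transcripts on the same array, so they are not separate evidence. No biological explanation was tested, and the injected mouse may still have responded: its interferon-stimulated genes averaged 1.35 over mock.

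Mock replicate 2 had more signal for interferon-stimulated genes than the other mock arrays, with a mean 0.85 above the group's, against -0.43 and -0.42, and so had other lists, among them reactive astrocytes and MHC class I (0.57 for each, the other mock arrays between -0.37 and -0.20), GTPases and regulators (0.54), chemokines (0.48), activated macrophage or microglia (0.47), infiltrating monocytes (0.44) and cell cycle (0.42). A vector-injected mouse labelled as mock is argued against, since the 5 vector arrays with controls in order lay between 2.39 and 2.90 for interferon-stimulated genes, a gap of 1.54 against a range of 0.514, although a first form of this test, which also counted HS replicate 1 at 1.35, did not decide. RNA of a vector-injected sample mixed in stays open for the interferon-stimulated genes, not for cell cycle, where no vector array lay above 0.35. Homeostatic microglia and MHC class II genes on mock replicate 2 also lay above every vector array (0.20 against -0.22 or less, and 0.40 against 0.22 or less). Mixed-in RNA would bring 1 share of every induced gene, and the shares of the MC+HS response ran from -5.97% for Chil3 and -0.789% for Gzmb to 43.4% for Ifi27l2a and 60.2% for Lgals3. Departures from a common share were 1.29 times those expected from the spread of the other mock arrays for the interferon-stimulated list (bootstrap over genes, which are not independent, 95% interval 0.614 to 2.82) and 1.90 times for 77 listed genes at least 4-fold higher (0.918 to 4.38), or 1.76 (0.864 to 3.84) and 2.36 times (96 genes, 1.23 to 4.84) with HS replicates 2 and 3 as the source, so that only the last lay above 1. A response of that mouse to the mock preparation also stays open and untested, and without HS replicate 1 and mock replicate 2, 1065 probe sets passed for HS against mock and 984 for MC+HS against mock.

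The real split gave 219 for HS against mock and the highest other split 0, with 1 of 10 splits as large, and 164 and 0 for MC+HS against mock, also with 1 of 10. Between the purifications the real split and the highest other gave 0, so that 10 of 10 splits were as large. With 10 splits a share under 0.05 cannot be reached.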
